A study of Mus musculus with 34 samples.

How the data were processed

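RNA sequencing was done on messenger RNA bound to tagged ribosomes of inhibitory interneurons of mice at postnatal day 60. The RiboTag method places an HA epitope on the ribosomal protein Rpl22 in cells that express Cre recombinase, and ribosomes with their mRNA are then pulled down with an antibody to HA. Cre was driven from the Pvalb gene, which marks parvalbumin (PV) interneurons, or from the Sst gene, which marks somatostatin (SST) interneurons. The labels give cortex and hippocampus as the tissue, while the extraction protocol in the labels speaks of cortices, so the part of the brain behind each library is known only to that extent.

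Per the submitters' processing notes, the tools were cutadapt 1.18, STAR 2.5.2a, HTSeq 0.11.0 and DESeq2, and the genome builds mm10 and GRCm39 were named. The notes give no role, order or batch for these tools and builds, and library strandedness is not given in the sources used here. The deposited tables hold 1 batch each, and the labels name batches 1 to 5. For batch 1 the authors deposited expected counts per gene symbol, which they had estimated from the reads before deposit; the notes state no further scaling of these values. Of them 11.3% were not whole numbers, and they were rounded to whole numbers before any test. For batches 2 to 5 the authors deposited whole-number read counts per gene, with no normalization in the values. The batch 2 table listed 11808 genes and left out most genes with few counts. The tables of batches 3, 4 and 5 listed 53465 genes each, and that of batch 1 listed 24371.

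Groups, batches and replicate numbers were taken from the sample titles. No column of values per sample was left unused (0 columns). Total counts per library ran from 12135905 to 20990658 in batch 1, from 4933110 to 18413104 in batch 2, from 10096035 to 27282912 in batch 3, from 15578007 to 20271874 in batch 4 and from 22249178 to 24623907 in batch 5. Among 37 pairs of replicates, 0 pairs were identical, and the smallest chi-square per degree of freedom between counts of a pair was 6.18, so each library was counted as 1 replicate. The labels do not say which libraries came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Floors and intervals cover counting error only, since reads carry no molecular identifiers.

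The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with robust dispersion, TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment at a threshold of 0.05. All libraries of a table shared the estimate of the spread. The comparisons were PTZ against saline (PV in batch 1, SST in batch 2), contextual fear conditioning against home cage (PV in batch 3, SST in batch 4) and libraries labelled Nr4a1 cKO against home cage (PV within batch 3, SST in batch 5 against batch 4). In the last of these, batch and genotype coincide and cannot be told apart. SST and PV saline libraries were compared within batch 2, and 2 comparisons between batches (PV saline of batch 2 against batch 1, and SST saline of batch 2 against SST home cage of batch 4) served as a rough scale for what a change of batch does. Their tables also differ in the genes listed and, for batch 1, in the kind of counts, so this scale holds more than a change of batch. Differences between responses were tested as contrasts of contrasts over the genes common to both tables. Expression levels are given as CPM, that is, counts scaled to a common library total, after TMM scaling over the libraries fitted together, so the level of a gene in a library can differ slightly between comparisons. Standard errors were the absolute log2 fold change divided by the square root of F.

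Gene lists fixed before the data were examined were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. Adjusted values were computed over the lists of a comparison, and each count of called members was also made with p-values adjusted over the list alone. Only lists reported by name in the results are described there; over the 6 main comparisons 65 of the list tests passed with camera, 5 with an estimated correlation and 21 with fry. Overlaps of called genes were tested with a two-sided Fisher exact test against independent lists, and chance values for comparisons that share home cage libraries were found from 20 simulations of unchanged groups. Genes are named by a rule fixed in advance: Nr4a1, Fos, Pvalb and Sst in each comparison; up to 10 called genes per direction with the largest change, at a mean of at least 5 CPM and with no overlap between groups (5 per direction and no overlap rule for differences of responses); and, from each list, up to 4 called members or, where none passed, up to 2 with the smallest p. Outside this rule, the remaining called genes are also named for SST PTZ, PV cKO and SST CFC minus PTZ. For these comparisons they enter the alternatives and left-out fits only through the counts of called genes. Tallies of named-gene values leave them out there. Gene positions are those of GRCm38 in the GENCODE vM21 annotation, which may not be the annotation the authors used. Of 511 named symbols, 508 had a single position there. Genes named in the results that share over 10% of their 50-base sequence windows with another gene are marked there as uncertain, a limit set after the shares were seen; members of lists counted only as a group were not checked.

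Alternatives tried were RLE size factors, no filter on low counts, a minimum of 1 CPM, the DESeq2 1.42.0 Wald test, limma voom with quality weights, fits of only the compared groups, the replicate number as a block, and leaving out each library in turn. Those added after the data were seen were a sex term (from the Y-linked gene Ddx3y at 5 CPM), fits without doubted libraries, a vascular marker score as a covariate, and the SST cKO comparison without mitochondrial, ribosomal protein and CT010467.1 transcripts. Each test was tested on simulated data in which 200 genes were changed by 1.5-, 2- or 4-fold, drawn from the means and depths of the real libraries. Of the genes changed 4-fold, edgeR recovered 81.5% in PV PTZ, 92.4% in SST PTZ, 74.2% in PV CFC, 75.8% in SST CFC, 73% in PV cKO and 60.3% in SST cKO simulations. For a 2-fold change these shares were 18.5%, 42.4%, 43.9%, 41% and 21.9%, and 37.5% for SST cKO. False calls in these simulations numbered 3 of 68 with edgeR and 20 of 100 with DESeq2 in PV PTZ, 5 of 104 and 23 of 147 in SST PTZ, 4 of 87 and 39 of 143 in PV CFC, 7 of 93 and 31 of 129 in SST CFC, 0 of 65 and 23 of 111 in PV cKO, and 4 of 73 and 31 of 123 in SST cKO. Limma voom made 0 of 56, 4 of 102, 6 of 85, 5 of 80, 1 of 58 and 2 of 70 in the same order. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.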

Results

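Ribosome-bound mRNA was profiled in 34 RiboTag libraries that form 11 groups. No group holds RNA from before the pull-down, so PV cells and SST cells below name the Cre line of the libraries. PV libraries came from mice given saline (n = 3) or pentylenetetrazol, PTZ (n = 4), in batch 1, from mice given saline (n = 2) in batch 2, and in batch 3 from mice kept in the home cage (n = 3), mice put through contextual fear conditioning, CFC (n = 3), and home cage mice labelled Nr4a1 cKO (n = 3). SST libraries came from mice given saline (n = 4) or PTZ (n = 3) in batch 2, from home cage (n = 3) and CFC (n = 3) mice in batch 4, and from home cage mice labelled Nr4a1 cKO (n = 3) in batch 5. PTZ blocks GABA receptors and excites neurons throughout the brain, and CFC pairs a context with foot shocks. The study set out to find genes that answer associative learning in these cells, with PTZ as a reference for broad excitation, and to profile cells that lack Nr4a1. Totals ranged from 4933110 to 27282912 counts per library. The shallowest were the PV saline libraries of batch 2, with 6161764 and 4933110 counts. In batch 3, PV home cage replicate 3 had 10096035 counts, 4.6% of them in the rRNA gene CT010467.1, against 1.39% and 2.45% in the other home cage libraries.

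Nr4a1, an orphan nuclear receptor induced by neuronal activity, lies on chromosome 15 from 101254269 to 101274795 (plus strand, GRCm38). Its level was 36.9, 4.62 and 8.35 CPM in the PV saline libraries of batch 1 and 118, 109, 110 and 90.6 CPM after PTZ. PV saline libraries of batch 2 had 33 and 9.62 CPM. Within batch 3, PV home cage libraries had 5.08, 7.35 and 11.3 CPM, PV CFC libraries 57.4, 56.6 and 64.3 CPM, and the PV libraries labelled Nr4a1 cKO 6.73, 16.5 and 7.69 CPM. SST saline libraries had 44.3, 32.3, 14.7 and 30.2 CPM and SST PTZ libraries 88.5, 118 and 102 CPM. SST home cage libraries had 23.4, 15.2 and 13.8 CPM, SST CFC libraries 85.7, 104 and 93 CPM, and the SST libraries labelled Nr4a1 cKO 14.8, 11.4 and 17.7 CPM. Nr4a1 thus had no lower level that passed a test in libraries labelled Nr4a1 cKO: the log2 fold change against home cage was 0.38 ± 0.35 (SE) in PV (adjusted p = 0.592, edgeR) and -0.30 ± 0.22 in SST (adjusted p = 0.511). The tables count reads over the whole gene, so exons outside a deleted part are included and these levels do not check the genotype labels.

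**Figure D1:**
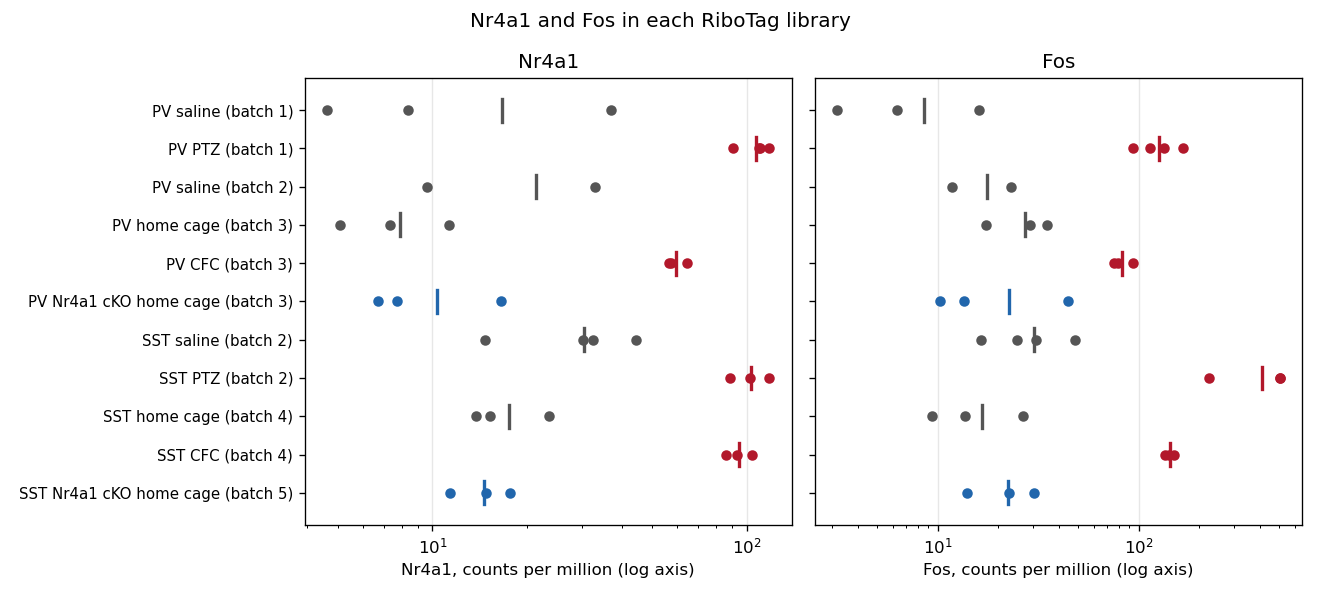
Nr4a1 and Fos in CPM (log axis) in each library, by group, with 1 point per library. Nr4a1 ranged from 56.6 to 64.3 in the PV CFC libraries and from 5.08 to 11.3 in the PV home cage libraries.

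PTZ raised 4 immediate early genes in PV libraries. Npas4, a transcription factor induced by calcium entry, went from 5.75 ± 4.21 CPM (SD, n = 3) in saline to 158 ± 46.2 CPM (n = 4), a log2 fold change of 4.80 ± 0.48 (SE; adjusted p = 0.0131, edgeR). The AP-1 subunits Fosb and Fos rose by 4.42 ± 0.50 (adjusted p = 0.02) and 3.91 ± 0.51 (adjusted p = 0.0395), and Btg2, a regulator of cell growth, by 3.41 ± 0.40 (adjusted p = 0.02). These were 4 of 13598 genes tested, with 0 lower; 1875 genes had an unadjusted p under 0.05, against 680 expected, and DESeq2 called 215 and limma voom 69 genes. Nr4a1 had a log2 fold change of 2.69 ± 0.59 that missed the threshold (adjusted p = 0.239). Pvalb, the calcium buffer that names PV cells, was at 80 ± 36.2 CPM after PTZ and 20 ± 3.53 CPM in saline (log2 2.00, adjusted p = 0.159), while Sst differed by 0.03 (adjusted p = 0.968). Sst was at 48.6 ± 12.5 CPM in saline, above Pvalb, and at 49.5 ± 18.4 CPM after PTZ, below it. Whether RNA from other cells adds to the 4 rises was not tested. All 4 calls were lost when any of PTZ replicates 2, 3 or 4 or saline replicate 4 was left out (0 genes called), although the log2 values stayed close (Npas4 4.53 to 4.87, Fosb 4.32 to 4.56, Fos 3.73 to 4.03, Btg2 3.17 to 3.44). The count was 2 without saline replicate 3, 7 without PTZ replicate 1 and 14 without saline replicate 1, where Nr4a1 passed (log2 4.04, adjusted p = 0.000691). A sex term, or leaving out PTZ replicates 1 and 2, also gave 0 calls.

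Of the 32 rapid activity-induced genes on the fixed list, 4 rose in PV cells after PTZ and 26 did so when adjusted over the list alone, and 30 had positive values (median log2 1.65). The list passed with camera (adjusted p = 1.17e-22) but not with the correlation estimated (adjusted p = 0.328 with an estimated correlation), and its fry adjusted p was 0.0326. Among the 44 delayed activity-regulated genes 0 were called by edgeR and 10 passed adjusted over the list alone, led by Ptgs2, an inducible cyclooxygenase (log2 3.46 ± 0.54, adjusted p = 0.131). That list had a camera adjusted p of 6.01e-06 and an adjusted p = 0.548 with an estimated correlation. Transcripts of other cell types lay higher in the same PTZ libraries: 16 of 16 microglia markers, 15 of 16 astrocyte markers, 19 of 20 oligodendrocyte lineage markers and 16 of 19 vascular and mural markers were positive, with median log2 values of 1.63, 0.53, 0.69 and 0.89. Each of these 4 lists passed with camera (adjusted p from 1.75e-05 to 0.00145), none passed with an estimated correlation (each adjusted p = 0.548 with an estimated correlation), and 0 of their members were called by edgeR, with 0, 0, 1 and 1 higher adjusted over the list alone. On the negative side, 69 of 70 nuclear-encoded subunits of oxidative phosphorylation (median -0.37), 24 of 28 voltage-gated potassium channels (median -0.49) and 18 of 22 PV interneuron markers (median -0.58) had negative values, again with camera adjusted p from 3.26e-08 to 0.000129 and an adjusted p = 0.548 with an estimated correlation. Adjusted over the list alone, 0, 0 and 2 of them passed, and the 2 PV markers were higher.

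In SST cells PTZ raised 17 genes and lowered 0 of 11784 tested. The strongest were transcription factors of the immediate early class: Fosb went from 7.15 ± 1.75 CPM (SD, n = 4) to 303 ± 94.5 CPM (n = 3), a log2 fold change of 5.40 ± 0.25 (SE; adjusted p = 6.04e-07, edgeR), Npas4 rose by 4.11 ± 0.32 (adjusted p = 0.000107), Fos by 3.77 ± 0.37 (adjusted p = 0.000446) and Junb by 3.37 ± 0.32 (adjusted p = 0.000381). The zinc finger factors Egr2, Egr4, Egr1 and Egr3 rose by 2.74, 2.73, 1.70 and 1.61. Arc, which acts in trafficking of AMPA receptors, rose by 2.15 ± 0.17 to 534 ± 108 CPM, and Ptgs2 by 2.73 ± 0.22. Phosphatases that switch off MAP kinases rose too, Dusp1 by 2.48 and Dusp6 by 1.48, as did the mRNA decay factor Zfp36 (2.71), Btg2 (2.86), the small GTPase Rasl11a (1.47), the thyroid hormone deiodinase Dio2 (0.90) and the G-protein regulator Rgs4 (0.76). At an unadjusted p under 0.05 there were 511 genes against 589 expected. Nr4a1 was at 103 ± 14.7 CPM after PTZ and 30.4 ± 12.2 CPM in saline, a log2 fold change of 1.76 ± 0.35 that missed the threshold (adjusted p = 0.143). DESeq2 called 38 genes, limma voom 74 and a fit of the compared groups alone 38, and each of the first 2 included all 17. With any single library left out, 13 to 17 genes were called. The calls lost included Btg2 without saline replicate 2 (adjusted p = 0.0688), Egr4 without saline replicate 3 (0.0576), and Btg2 and Rgs4 without PTZ replicate 1 (0.071 and 0.0524) or replicate 3 (0.0667 and 0.0527); Egr4 was also lost without PTZ replicate 3 (0.0656).

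The gene lists gave the same picture for SST cells after PTZ. Of 29 rapid activity-induced genes 11 rose, 20 adjusted over the list alone, with a camera adjusted p of 2.96e-54, an adjusted p = 0.0124 with an estimated correlation and a fry adjusted p of 0.00216. Among 43 delayed activity-regulated genes 2 rose (7 adjusted over the list alone; camera 3.74e-13, adjusted p = 0.0457 with an estimated correlation), and among 15 MAP kinase feedback regulators 2 rose (5 adjusted over the list alone; camera 8.42e-09, adjusted p = 0.0228 with an estimated correlation). The Nr4a family (Nr4a1, Nr4a2 and Nr4a3) had 0 members called over all genes by edgeR and 3 adjusted over the list alone (camera 8.42e-09, adjusted p = 0.0457 with an estimated correlation). Nr4a2 and Nr4a3 had log2 values of 0.91 and 1.02. Heat shock proteins and chaperones had 19 of 22 positive values with a median of 0.20, 0 called over all genes and 4 adjusted over the list alone (camera 9.16e-07, adjusted p = 0.025 with an estimated correlation), led by the endoplasmic chaperone Hspa5 (0.52 ± 0.12). Ribosomal proteins had a median of -0.27 (58 of 63 negative; camera 8.35e-12, adjusted p = 0.355 with an estimated correlation), and 0 of them were called.

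**Figure D2:**
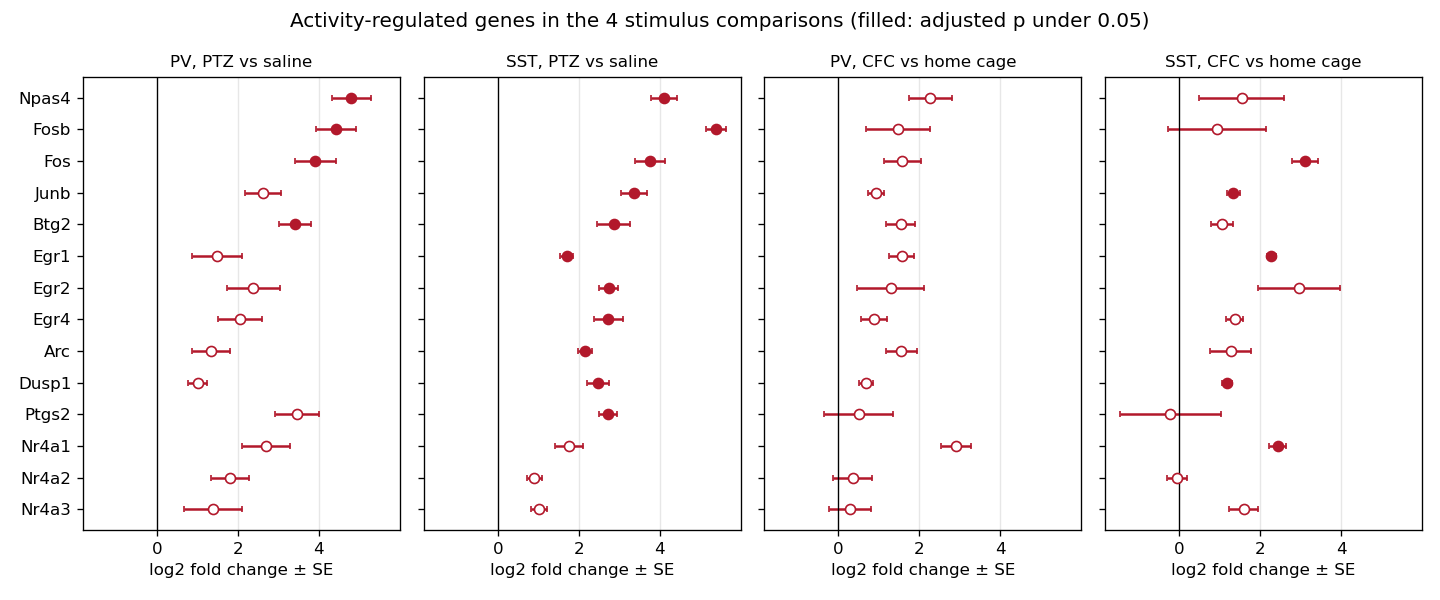
Log2 fold changes with SE of activity-regulated genes in the 4 stimulus comparisons, filled where the adjusted p was under 0.05. Fosb stood at 5.40 in SST cells after PTZ and at 0.93 in SST cells after CFC.

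The 4 genes called in PV cells after PTZ (Btg2, Fos, Fosb and Npas4) were all among the 17 called in SST cells, against 0.00583 expected for independent lists (Fisher exact p = 3.08e-12, of 11669 genes tested in both). Across genes the log2 fold changes of both cell types had r = 0.38 (Spearman's rho = 0.342), and genes are not independent replicates. The test of the difference between the responses of SST and PV cells to PTZ gave 0 genes of 11743 by edgeR, with 602 at an unadjusted p under 0.05 against 587 expected, and 1 gene by DESeq2. The smallest p belonged to Pvalb, whose log2 response in SST minus PV was -2.86 ± 0.46 (adjusted p = 0.112). It passed without PV PTZ replicate 2 (adjusted p = 0.0106, 1 gene called). For Nr4a1 the difference was -0.97 ± 0.73 (adjusted p = 0.838) and for Fos -0.18 ± 0.63 (adjusted p = 0.966).

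CFC raised no gene in PV cells past the threshold, and Nr4a1 came closest. It went from 8.06 ± 3.35 CPM (SD, n = 3) in the home cage to 59.1 ± 4.53 CPM (n = 3), a log2 fold change of 2.90 ± 0.37 (SE; adjusted p = 0.0594, edgeR). Egr1 was at 179 ± 19.2 CPM against 60.7 ± 10.2 CPM (log2 1.56, adjusted p = 0.186) and Fos at 82.2 ± 9.89 CPM against 27.6 ± 9.37 CPM (log2 1.58, adjusted p = 0.186). The edgeR test called 0 of 15150 genes, with 2834 at an unadjusted p under 0.05 against 758 expected, while DESeq2 called 745, limma voom 732 and edgeR without a filter 1032. Nr4a1 passed in 6 of 8 alternatives. It also passed without home cage replicate 1 (log2 2.65, adjusted p = 0.0191; 1481 genes called) and without home cage replicate 3 (log2 3.25, adjusted p = 0.0383; 2 genes called).

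Of 31 rapid activity-induced genes, 0 were called by edgeR in PV cells after CFC, 9 passed adjusted over the list alone and 23 were positive (median 0.66; camera 9.23e-05, adjusted p = 0.667 with an estimated correlation). Larger sets of housekeeping transcripts lay on the other side. Among the 70 nuclear-encoded subunits of oxidative phosphorylation 66 had negative values (median -0.68), 59 passed adjusted over the list alone and 0 over all genes, with Ndufa1 of complex I at -0.97 ± 0.23 (camera 2.4e-25, adjusted p = 0.667 with an estimated correlation). All 62 cytosolic ribosomal proteins had negative values (median -0.65), and 53 passed adjusted over the list alone (camera 2.32e-23, adjusted p = 0.717 with an estimated correlation). The same lists had medians of -0.55 and -0.54 in the PV libraries labelled Nr4a1 cKO, which were compared with the same 3 home cage libraries. PV home cage replicate 3, the shallowest library of the batch, was 1 of those 3.

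In SST cells CFC raised 5 activity-regulated genes. Egr1 went from 90.9 ± 13.4 CPM (SD, n = 3) to 441 ± 19.2 CPM (n = 3), a log2 fold change of 2.28 ± 0.11 (SE; adjusted p = 0.000177, edgeR). Nr4a1 rose by 2.43 ± 0.21 (adjusted p = 0.011), from 17.5 ± 5.22 to 94.4 ± 9.24 CPM, Fos by 3.11 ± 0.33 (adjusted p = 0.0275), Junb by 1.34 ± 0.16 (adjusted p = 0.0438) and Dusp1 by 1.19 ± 0.12 (adjusted p = 0.0275). One gene was lower: Acta2, the actin of smooth muscle, fell by 4.17 on the log2 scale (adjusted p = 0.0438), from 22.7, 67.7 and 78.6 CPM in the home cage libraries to 3.13 ± 1.07 CPM. Sst was at 5930 ± 205 and 5750 ± 206 CPM (log2 0.04, adjusted p = 0.997). Of 14614 genes tested 814 had an unadjusted p under 0.05, against 731 expected; DESeq2 called 102 genes, which included all 6, and limma voom 6, of which 5 were shared. Egr1 alone was called when any library other than home cage replicate 1 was left out (1 gene each time: CFC replicates 1, 2 and 3 and home cage replicates 2 and 3), whereas 37 genes were called without home cage replicate 1. Where the calls were lost the log2 values stayed close (Nr4a1 2.285 to 2.498, Fos 2.821 to 3.151, Junb 1.248 to 1.369, Dusp1 1.105 to 1.252, Acta2 -3.85 to -4.381). With a vascular score as covariate 1 gene was called, and Nr4a1 missed the threshold at a log2 fold change of 1.91. That score was lower in every CFC library (at most 2.7) than in any home cage library (at least 3.3). It largely coincides with CFC, so calls lost with it say little.

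Of 29 rapid activity-induced genes 5 rose in SST cells after CFC, 7 adjusted over the list alone (camera 3.63e-13, adjusted p = 0.103 with an estimated correlation, fry 0.0179). In the Nr4a family, Nr4a1 rose and Nr4a3 had a log2 value of 1.60 ± 0.36 that passed adjusted over the list alone, 2 of 3 members in all (camera 4.72e-05, adjusted p = 0.137 with an estimated correlation). All 20 vascular and mural cell markers had negative values with a median of -2.35; 1 fell over all genes and 16 adjusted over the list alone (camera 1.99e-20, adjusted p = 0.175 with an estimated correlation, fry 0.107). Other cell types lay in the same direction, with medians of -0.60 for 16 astrocyte markers (camera 1.38e-05, adjusted p = 0.301 with an estimated correlation) and -0.37 for 15 microglia markers (camera 0.0203, adjusted p = 0.199 with an estimated correlation). Col4a2, a collagen of the vessel basement membrane, was at 7.41 ± 1.81 CPM after CFC and 27.6 ± 10.2 CPM in the home cage (log2 -1.90, adjusted p = 0.338). The mean log2(CPM + 1) of the vascular markers was 3.3, 5.21 and 4.36 in the home cage libraries and 2.53, 2.7 and 2.24 in the CFC libraries. Ribosomal proteins (61 of 62 positive, median 0.15) and subunits of oxidative phosphorylation (67 of 70 positive, median 0.11) had small values of the other sign, with camera adjusted p of 1.36e-10 and 1.32e-09 and adjusted p = 0.442 and 0.516 with an estimated correlation.

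**Figure D3:**
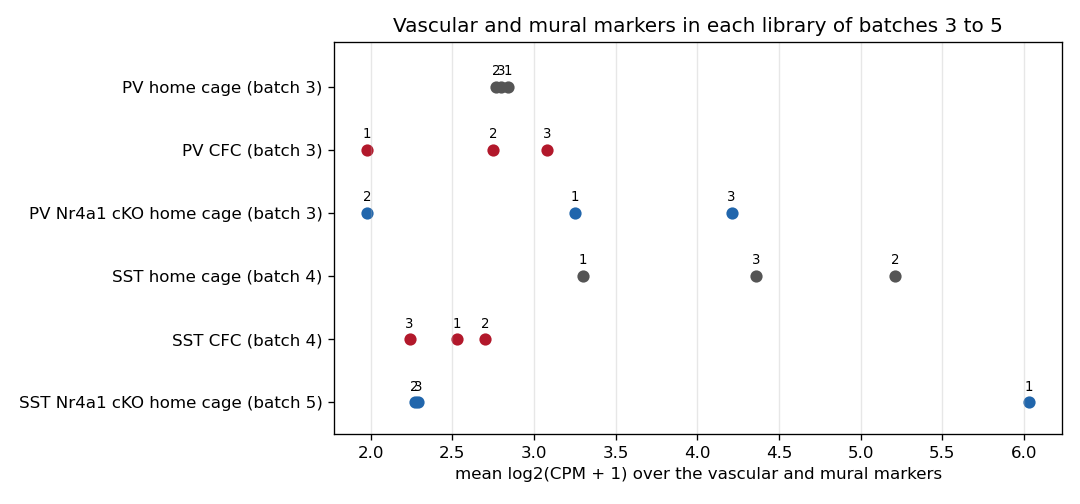
Mean log2(CPM + 1) of the vascular and mural cell markers in each library of batches 3 to 5, with 1 point per library. The SST libraries labelled Nr4a1 cKO ranged from 2.27 to 6.03.

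Both stimuli raised Egr1, Fos, Dusp1 and Junb in SST cells: 4 of the 5 genes higher after CFC were among the 17 higher after PTZ, against 0.00763 expected (Fisher exact p = 1.86e-11, of 11137 genes). Across all genes the log2 fold changes had r = -0.0848. The test of the difference found 10 genes with a lower response to CFC than to PTZ and 0 with a higher one, of 11428 tested. Among them Fosb had a log2 response of 0.93 to CFC and 5.40 to PTZ (difference -4.37 ± 0.75, adjusted p = 0.0433; -3.15, adjusted p = 0.547, without home cage replicate 2), against home cage levels of only 0.745, 1.89 and 0 CPM, Junb 1.34 and 3.37 (difference -2.00 ± 0.36, adjusted p = 0.0433) and Rgs4 -0.09 and 0.76 (difference -0.82 ± 0.14, adjusted p = 0.0433). Junb was at 1.56 CPM in saline and 16.2 CPM after PTZ. In batch 4 it was at 44.5 CPM in the home cage and 113 CPM after CFC. The smaller log2 response of Junb to CFC thus went with a higher starting level in another batch. The other 7 were Acta2 (-4.81), the lipid desaturase Degs2 (-4.11), the podocalyxin gene Podxl (-3.89), Ahnak (-3.59), the pericyte receptor Pdgfrb (-3.55), the collagen Col4a2 (-3.10) and the intermediate filament Vim (-3.04), with log2 responses to CFC from -1.90 to -4.17. Their responses to PTZ ran from -0.004 to 0.68, apart from Col4a2 (1.24). Each of the 7 was lower in home cage replicate 1 than in replicates 2 and 3 (Podxl 7.68, 56.2 and 28.9 CPM). The vascular marker score was too (3.3, 5.21 and 4.36). A response of SST cells therefore cannot be told apart from vascular RNA in those home cage libraries for these 7 genes. Nr4a1 did not differ past the threshold (0.70 ± 0.49, adjusted p = 0.79). DESeq2 called 62 genes. The count was 0 without saline replicate 1, 2 or 4, any PTZ library or CFC replicate 3, 1 without CFC replicate 2 or home cage replicate 2, 2 without saline replicate 3 or CFC replicate 1, 5 without home cage replicate 3 and 59 without home cage replicate 1. Where calls were lost the differences stayed close for Junb (-1.855 to -2.164), Rgs4 (-0.7659 to -0.8517) and Acta2 (-4.467 to -5.161). Those of Podxl and Ahnak moved to -3.147 and -2.814 without home cage replicate 2.

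In PV cells 1 gene differed between the responses: Fut10, a fucosyltransferase, with a higher log2 response to CFC than to PTZ by 3.17 ± 0.47 (adjusted p = 0.0259, edgeR), of 14257 genes tested. Fut10 was also called higher in PV libraries labelled Nr4a1 cKO, from home cage mice, against the same home cage libraries. A response to CFC therefore cannot be told apart from a low Fut10 level in those shared libraries. Fos had a difference of -2.39 ± 0.70 and Npas4 of -2.60 ± 0.68 (both adjusted p = 0.295), and Nr4a1 of 0.14 ± 0.70 (adjusted p = 0.953). With RLE size factors the median log2 difference over all genes moved by -0.109, and Fut10 remained the 1 call. DESeq2 called 40 genes, and 2 genes were called without saline replicate 1, 9 without home cage replicate 1 and 2 without home cage replicate 3. The Fut10 call was lost without PTZ replicate 1, 3 or 4, saline replicate 3 or 4, any CFC library or home cage replicate 2 (adjusted p from 0.0515 to 0.18), although its log2 difference stayed close (2.872 to 3.255). None of the 4 genes raised by PTZ was called after CFC in PV cells, where edgeR called 0 genes, and the log2 fold changes had r = 0.0727 across 12364 genes.

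The response to CFC in SST cells minus that in PV cells gave 0 of 16081 genes by edgeR, with 2452 at an unadjusted p under 0.05 against 804 expected, 327 genes by DESeq2 881 by edgeR without PV home cage replicate 1 and 1 without PV home cage replicate 3. Nr4a1 differed by -0.42 ± 0.46 (adjusted p = 0.709) and Fos by 1.58 ± 0.66 (adjusted p = 0.277). Subunits of oxidative phosphorylation had 67 of 70 positive differences, with 61 called adjusted over the list alone, and ribosomal proteins 62 of 62, with 58. In PV home cage replicates 1, 2 and 3 Ndufa1 was at 399, 618 and 850 CPM, and the share of CT010467.1 rose in the same order (1.39%, 2.45% and 4.6%). Whether these list differences come from the PV home cage libraries rather than from the response to CFC was not tested. At an adjusted p under 0.1, Nr4a1 was the 1 gene called higher after CFC in both cell types (Fisher exact p = 0.000425).

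PV libraries labelled Nr4a1 cKO had 15 genes higher and 6 lower than home cage libraries of the same batch. Most of the higher genes make, carry or charge amino acids. Psat1, an enzyme of serine synthesis, went from 24.8 ± 3.06 CPM (SD, n = 3) to 99.2 ± 7.73 CPM (n = 3), a log2 fold change of 2.00 ± 0.17 (SE; adjusted p = 0.00077, edgeR), and Phgdh, the first enzyme of that pathway, rose by 3.00 ± 0.28 (adjusted p = 0.00123). Psph, which completes serine synthesis, rose by 1.17, the mitochondrial one-carbon enzymes Mthfd2 and Shmt2 by 1.45 and 1.39, and asparagine synthetase Asns by 1.04. The transporters Slc7a5 and Slc7a3 were higher as well, the first by 1.39 and the second at 11.3 ± 2.82 CPM with 0 counts in all 3 home cage libraries, at least 165-fold higher against a floor of 3 counts over the group. Chac1, which degrades glutathione, and the stress sensor Sesn2 rose by 1.52 and 1.42, and the tRNA synthetases Vars and Mars by 1.10 and 1.08. The remaining higher genes were the chloride channel protein Clic4 (1.56), Fut10 (2.25) and Ndufs5 (1.56). The lower genes were Hist3h2ba (-2.27), BC002163 (-1.56), the muscle titin-binding gene Tcap (-1.38), the actin-sequestering thymosin Tmsb4x (-1.24), Fam114a1 (-1.18) and Gm20305, whose ratio is not given here.

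Ndufs5 and BC002163 are uncertain, since 72.6% of the 270 50-base windows of BC002163 also occur in Ndufs5, and the same holds for Phgdh, which shares 47.8% of its windows, mostly with the pseudogene Gm7901. Hist3h2ba, which shares 22.1% with Hist3h2bb-ps, and Gm20305, which shares 100% with other genes, are uncertain too. Pvalb was at 1050, 1350 and 156 CPM in the libraries labelled Nr4a1 cKO and at 155, 190 and 163 CPM in home cage libraries (log2 2.33 ± 0.61, adjusted p = 0.151). The test covered 15150 genes, of which 2699 had an unadjusted p under 0.05 against 758 expected; DESeq2 called 669 genes, 20 of them shared, limma voom 43, 19 of them shared, and a fit of the compared groups alone 10. Counts moved to 7 without cKO replicate 1, 9 without home cage replicate 2 and 1224 without home cage replicate 1. Calls lost without cKO replicate 1 included Slc7a3 (adjusted p = 0.0979), Sesn2 and Slc7a5 (each 0.0892), Shmt2 (0.0653), Tmsb4x and BC002163 (each 0.084), Tcap (0.102), Hist3h2ba (0.157) and Fam114a1 (0.229), and those lost without home cage replicate 2 included Slc7a3, Sesn2, BC002163 and Fam114a1 (each 0.072), Shmt2 (0.0538), Hist3h2ba (0.159), Tcap and Ndufs5 (each 0.177). Without home cage replicate 3 the calls of Hist3h2ba (0.12), Tcap (0.123) and Fam114a1 (0.0874) were lost, without cKO replicate 2 those of Ndufs5 and Fam114a1 (each 0.0693), and without cKO replicate 3 those of Slc7a5 (0.0564), Ndufs5 (0.0825), Hist3h2ba (0.119), Tcap and Fam114a1 (each 0.13).

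Among 31 rapid activity-induced genes 0 were called by edgeR in the PV libraries labelled Nr4a1 cKO and 1, the AP-1 subunit Jun, was lower adjusted over the list alone (log2 -0.74, adjusted p = 0.0904 over all genes; camera 0.74). The stress-induced factor Atf3 of that list had a log2 value of 2.57 ± 0.73 (adjusted p = 0.151) and the delayed gene Vgf, a secreted neuropeptide precursor, 0.73 ± 0.16 (adjusted p = 0.116), so missing calls do not show that these genes were unchanged. Subunits of oxidative phosphorylation had 65 of 70 negative values with a median of -0.55 and 50 lower adjusted over the list alone (camera 1.03e-19, adjusted p = 0.733 with an estimated correlation). The 1 called member, Ndufs5, rose. Ribosomal proteins had 61 of 62 negative values with 0 called over all genes or adjusted over the list alone (camera 3.59e-15, adjusted p = 0.733 with an estimated correlation). Markers of other cells lay higher: 19 of 20 oligodendrocyte lineage markers (median 0.90; camera 6.09e-05) and 15 of 16 astrocyte markers (median 0.64; camera 0.00404) were positive, each with an adjusted p = 0.733 with an estimated correlation 0 called over all genes, and 2 and 3 higher adjusted over the list alone. The 20 vascular and mural markers had a median of 1.22. Their mean log2(CPM + 1) was 3.25, 1.98 and 4.21 in these libraries and 2.77 to 2.84 in the home cage libraries. The 4 genes raised by PTZ in PV cells had a median log2 value of 0.02 in the PV libraries labelled Nr4a1 cKO (camera p = 0.886, fry p = 0.9, p = 0.925 with an estimated correlation).

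A list of 50 amino-acid response genes and targets of ATF4, the transcription factor of that response, was written after the PV calls were seen. In PV libraries labelled Nr4a1 cKO 11 of its genes rose and 47 were positive (median 0.92, unchanged with Slc7a3 set at its bound); since those 11 prompted the list, no test of it is given for these libraries. The 39 others had a median of 0.68. In SST libraries with that label 10 rose, 16 adjusted over the list alone, and 48 were positive (median 0.44; camera p = 2.14e-11, p = 0.00702 with an estimated correlation). The list had a median of 0.18 after CFC in PV cells (0 called by edgeR; camera p = 0.00616, p = 0.195 with an estimated correlation) and camera p of 0.403, 0.682 and 0.223 in the PV PTZ, SST PTZ and SST CFC comparisons.

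Log2 fold changes of the PV cKO and PV CFC comparisons, which share their 3 home cage libraries, had r = 0.694 across 15150 genes. Unchanged groups simulated against those libraries gave a mean r of 0.52 (0.501 to 0.554 in 20 simulations). The simulations drew each gene on its own and left out shifts that many genes share in a library. Their range may therefore be too narrow to measure an excess. The covariance was 0.38 against a simulated mean of 0.136, a difference of 0.244, and 79.4% of genes had the same sign against 67% in the simulations. The 3 home cage libraries are too few to be divided between the comparisons, so part of the excess may come from the shared controls. No gene was called in both (0 shared, with 0 called after CFC), and at most 1 shared call arose in a simulation.

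**Figure D4:**
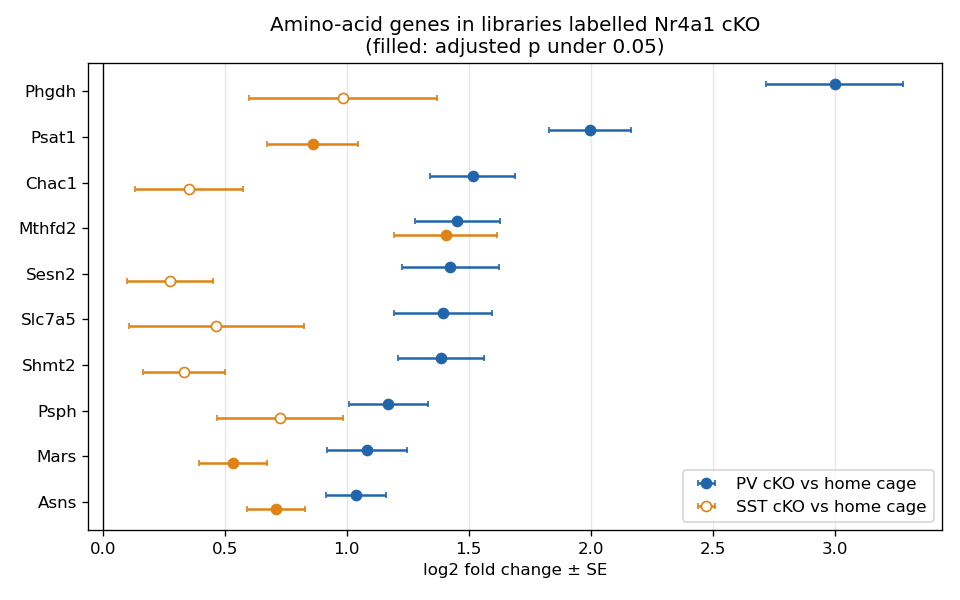
Log2 fold changes with SE of the called amino-acid genes other than Slc7a3 in PV and SST libraries labelled Nr4a1 cKO, filled where the adjusted p was under 0.05. Psat1 stood at 2.00 in PV and 0.86 in SST cells. Slc7a3 is not drawn, as its value in PV is a fitted one against 0 counts.

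SST libraries labelled Nr4a1 cKO differed from SST home cage libraries in 1252 genes, 543 higher and 709 lower of 15453 tested. Sst itself fell by 0.89 on the log2 scale (adjusted p = 0.000307, edgeR), from 5800 ± 246 CPM (SD, n = 3) to 3140 ± 232 CPM (n = 3). Other secreted peptides and their processing proteins fell with it, 8 of 28 on that list (10 adjusted over the list alone; camera 0.00019, adjusted p = 0.224 with an estimated correlation, fry 0.0137), among them Cck (-1.14), the proprotein convertase inhibitor Pcsk1n (-1.12) and chromogranin Chga (-0.54). Ribosomal proteins fell in 57 of 62 cases, with a median of -0.80 and Rps20 at -1.24 ± 0.11 (camera 1.41e-50, adjusted p = 0.224 with an estimated correlation, fry 0.00145). Subunits of oxidative phosphorylation fell in 41 of 70 cases, such as Cox8a by 1.19 (camera 4.2e-28, adjusted p = 0.271 with an estimated correlation), and all 7 mitochondrially encoded transcripts tested fell, mt-Nd4 from 214 ± 13.7 to 43.2 ± 10.4 CPM (median of the list -1.83; camera 1.22e-13, adjusted p = 0.224 with an estimated correlation). The rRNA gene CT010467.1 fell by 4.02, from 6300 ± 1140 to 389 ± 90.2 CPM.

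Single genes with large changes in SST libraries labelled Nr4a1 cKO included Tuba1c, an alpha tubulin, at 60.9 ± 3.77 CPM (SD, n = 3) against 1.19 ± 0.75 CPM (log2 5.67 ± 0.41 SE, adjusted p = 0.000137, edgeR), and Slc7a11, the cystine and glutamate exchanger, at 32.4 ± 1.32 CPM against 3.29 ± 2.51 CPM (log2 3.30 ± 0.51, adjusted p = 0.00383). Wdfy1 rose by 2.16, Nab1, a repressor that binds Egr proteins, by 1.88, and the ephrin Efna5 by 1.12. Smarcd1, a subunit of the SWI/SNF chromatin remodeler, fell by 2.41 (adjusted p = 3.81e-05), the cerebellar degeneration-related gene Cdr1 by 3.71 and Tmem87a by 2.52. Tuba1c shares 52.7% of its 50-base windows with other genes, mostly Tuba1b, and is uncertain, as are mt-Nd4 (62.2%, with Gm28439) and CT010467.1 (35.7%, with AY036118). Fos differed by 0.39 (adjusted p = 0.647) and Pvalb by -0.86 (adjusted p = 0.519). The 17 genes raised by PTZ in SST cells had a median of -0.05, 9 of them negative (camera p = 0.669, fry p = 0.837, p = 0.798 with an estimated correlation), and of 31 rapid activity-induced genes 1 rose (Arf4, 0.42) and 1 fell (Jun, -0.84), with the same counts adjusted over the list alone (camera 0.359). The call of Jun was lost without cKO replicate 2 (adjusted p = 0.0734), cKO replicate 3 (0.0661) or home cage replicate 1 (0.0633), and that of Arf4 without cKO replicate 2 (0.0613) or 3 (0.0651).

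Markers of other cells were lower in the same libraries: 3 of 16 astrocyte markers (median -0.80; camera 1.16e-05), 3 of 15 microglia markers (median -1.07; camera 0.00019), 4 of 20 oligodendrocyte lineage markers (median -0.68; camera 0.00019) and 3 of 23 excitatory neuron markers, among them Camk2a by -1.32 (camera 0.0043), fell. With adjustment over the list alone the numbers were 9, 6, 5 and 3, and with an estimated correlation the adjusted p was 0.224, 0.15, 0.271 and 0.224. Batch 5 holds only libraries labelled Nr4a1 cKO and batch 4 only others, so genotype and batch cannot be told apart in this comparison. The tables of batches 4 and 5 list 53465 genes each, whereas that of batch 2 lists 11808 and that of batch 1 holds expected counts. The comparisons that follow therefore mix batch with the form of the tables and are only a rough scale. SST saline libraries of batch 2 and SST home cage libraries of batch 4, which also differ in injection, differed in 9105 of 11395 genes (79.9%), with 4437 higher in batch 2 and 4668 lower. PV saline libraries of batch 2 and batch 1 differed in 889 of 11606 genes, 496 higher and 393 lower, with Pvalb at 309 ± 81.1 CPM (SD, n = 2) in batch 2 and 19.3 ± 3.27 CPM (n = 3) in batch 1 (log2 4.00, adjusted p = 0.000738, edgeR). The SST cKO count was 1142 without mitochondrial, ribosomal protein and CT010467.1 transcripts. It was 412 without cKO replicate 3, 426 without cKO replicate 2 and 806 without home cage replicate 1, and 2126 with DESeq2 and 2172 with limma voom, each sharing 1236 of the calls.

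Of the 15 genes higher in PV libraries labelled Nr4a1 cKO, 5 were also higher in the SST libraries with that label: Mthfd2, Psat1, Asns, Slc7a3 and Mars, against 0.556 expected (Fisher exact p = 0.000151, of 14579 genes tested in both). In SST cells they rose by 1.41, 0.86, 0.71, 1.03 and 0.53. Of the 5 genes lower in PV that were tested in both, 2 were lower in SST (Tmsb4x and Hist3h2ba, Fisher exact p = 0.0212). The log2 fold changes had r = 0.182 across genes. This overlap was added after the calls were seen.

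SST and PV saline libraries of batch 2 differed in 6254 of 11784 genes, 3065 higher and 3189 lower in SST. Sst was at 2570 ± 675 CPM (SD, n = 4) in SST and 61.2 ± 9.71 CPM (n = 2) in PV libraries (log2 5.39 ± 0.27 SE, adjusted p = 5.66e-08, edgeR), and Pvalb at 7.85 ± 2.79 and 302 ± 84 CPM (log2 -5.26 ± 0.26, adjusted p = 5.29e-08). Of 22 SST interneuron markers 19 were higher in SST libraries, and the count was the same adjusted over the list alone; of 22 PV interneuron markers 17 were lower, 18 adjusted over the list alone. Hpse, a heparanase, had 23.4 ± 2.05 CPM in SST libraries and no count in PV libraries, while Cox6a2, a muscle-type subunit of cytochrome oxidase, had 0.90 ± 0.49 and 107 ± 13.4 CPM (log2 -6.87). The potassium channel modifier Kcng4 and the parathyroid hormone-like gene Pthlh were lower in SST libraries by -5.66 and -5.10. Subunits of oxidative phosphorylation were lower in SST libraries for 68 of 70 genes, with a median of -2.24, and ribosomal proteins for 59 of 63, with a median of -1.53. The counts adjusted over the list alone were 68 and 59. Both lists also shifted together, though less, in PV libraries after CFC (medians -0.679 and -0.651). Whether the larger differences here come from the cell type or from the 2 PV libraries was not tested. The PV libraries were the shallowest of the series (6161764 and 4933110 counts), while the SST saline libraries had 13763931 to 18367658 counts. With voom 2880 genes were called, and with any single library left out 5476 to 6982.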

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

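Among 22 values tested in 2 groups of 4 libraries, 1 lay past the 95% limit of Dixon's test for a library far from the others. Pvalb in SST saline replicate 1 was at 12 CPM, with the nearest library at 6.71 and the lowest at 6.22 CPM, a gap of 0.915 of the range; chance gives about 1 in 20 such results. The tests on the 3 patterns below were all chosen after the patterns were seen, while the other splits of the libraries were planned.

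Amino-acid genes were higher in PV libraries labelled Nr4a1 cKO, with 11 genes of the list called. The shallow PV home cage replicate 3 is argued against as the whole cause: fitted without it, the list of 50 genes kept a median of 0.821 (0.924 with all libraries), with 47 of 50 positive, and the 39 genes not called before had a median of 0.663, with 36 of 39 positive. RNA from astrocytes stays open in PV libraries, since the median of the whole list lay 0.287 above that of the astrocyte markers, less than their SD of 0.527, although in PV cells after PTZ those markers had a median of 0.529 and the list one of -0.131, and in SST libraries labelled Nr4a1 cKO the medians were -0.804 and 0.441. RNA from vessels or oligodendrocytes was not tested as a source. Medians in the PV libraries labelled Nr4a1 cKO were 1.22 for vascular and mural markers and 0.896 for oligodendrocyte lineage markers. In SST libraries with that label they were 0.216 and -0.683. Loss of Nr4a1 stays open too, with a median of 0.711 for the 11 called genes in SST libraries with that label, where all 11 were positive and 5 called. Genotype cannot be told apart from batch there, and which animals gave the libraries is not in the labels.

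Genes close to Nr4a1 on chromosome 15 were called more often in SST libraries labelled Nr4a1 cKO than genes elsewhere, 18 of 111 within 5 Mb against 1218 of 15067 (Fisher exact p = 0.00448), among them Smarcd1; the p was 0.000319 within 2.5 Mb (17 of 83), 0.0145 within 10 Mb (19 of 131) and 0.1 within 20 Mb (27 of 246), so the excess did not pass at the widest distance. An effect of batch with no regard to position is argued against at 5 Mb, a width not set beforehand, since a share of 0.0116 of equally wide windows with at least 50 tested genes had as high a share of called genes. Reads shared among tubulin genes are argued against as the whole cause, with a Fisher exact p = 0.0339 within 5 Mb without them. A strain variant carried along with the targeted allele stays open: a share of 0.778 of these genes had the same sign in the PV libraries with that label, against 0.779 of called genes elsewhere. In PV libraries 0 of 111 genes around Nr4a1 were called by edgeR.

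Vascular and mural markers were lower in SST cells after CFC than in the home cage. Vascular RNA carried over in single libraries may account for this. The marker score had a range of 3.76 among the 3 SST libraries labelled Nr4a1 cKO, which were treated alike. CFC and home cage differed by 1.8, but in group means, which vary less than single libraries. That range rests on replicate 1 (6.03, against 2.27 and 2.29), and other groups had ranges from 0.0717 (PV home cage) to 2.24 (PV Nr4a1 cKO). In batch 4 every home cage library (at least 3.3) lay above every CFC library (at most 2.7), so the difference did not rest on a single library. Lower vascular transcripts throughout the tissue stay open. In PV cells after CFC the median was -0.13, with an SD of 0.681, which is 2.22 above that in SST cells. Those libraries are of another batch and Cre line, and vascular RNA in a pull-down does not measure its level in the tissue. What differs between the dissections was not tested.

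Other splits of the libraries into groups of the same sizes were counted for each comparison. For PTZ in SST cells the real split called 17 genes and the highest other 4, so that 1 of 35 splits was as large. That share of 0.0286 is the smallest that 35 splits allow. It makes chance less likely but does not exclude it. PTZ in PV cells had 4 genes, and 4 in the highest other split (2 of 35 as large), so chance cannot be excluded for the number of calls; the splits do not look at which genes were called, and all 4 were among the 17 of SST cells (Fisher exact p = 3.08e-12). SST saline of batch 2 against SST home cage of batch 4 had 9105 genes and 0 in the highest other split (1 of 35). With 3 libraries against 3, the 10 splits are too few for a share under 0.05: PV CFC had 0 genes, which every split reaches (10 as large), and at most 1 in another split, SST CFC 6 and 0 (1 as large), PV cKO 21 and 0 (1 as large) and SST cKO 1252 and 129 (1 as large).

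Differences of responses were counted over 100 splits each, which shuffle both stimuli and so stand for no response to either, not for equal responses. SST cells had 10 genes for CFC minus PTZ and at most 6 in another split (1 of 100 as large). That speaks against chance only for a case with no response to either stimulus, which the PTZ response already speaks against. In PV cells the 1 gene for CFC minus PTZ was reached in 6 of 100 splits, so chance cannot be excluded, and the highest other split had 375. The PTZ and CFC differences between cell types had 0 genes each, a count that every split reaches (100 of 100), so those shares say nothing; the highest other splits had 198 and 6. Splits with 375 and 198 genes point to some structure of the samples, and what it is was not tested.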

How the results depend on the processing

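The sex term, the fits without doubted libraries, the vascular score and the SST cKO fit without mitochondrial, ribosomal protein and CT010467.1 transcripts were chosen after the results were seen. No named gene or list test that passed the threshold in either fit changed direction under any alternative. Among those that passed in neither, named-gene values changed sign 3 times under alternatives set beforehand, 22 times under later ones and 30 times with 1 library left out. List tests did so 9 times. Of 4505 values of named genes under alternatives set beforehand 4153 kept their side of the threshold, 81 lost and 268 gained a call; with 1 library left out 6279 of 6746 did. DESeq2 called 215 genes (PV PTZ), 38 (SST PTZ), 745 (PV CFC), 102 (SST CFC), 669 (PV cKO), 2126 (SST cKO), 1 (PTZ, SST minus PV), 327 (CFC, SST minus PV), 40 (PV, CFC minus PTZ) and 62 (SST, CFC minus PTZ), with no adjusted p for 62 values of named genes; on simulated data it made more false calls than edgeR. Limma voom called 69 (PV PTZ), 74 (SST PTZ), 732 (PV CFC), 43 (PV cKO), 2172 (SST cKO) and 2880 (SST vs PV), and on simulated data its false calls were about as few as those of edgeR. Without a filter edgeR called 1032 (PV CFC), 11 (SST CFC), 1072 (PV cKO) and 708 (CFC, SST minus PV), and at 1 CPM 1 (PV CFC). Fits of the compared groups alone called 38 (SST PTZ), 2 (PV CFC) and 10 (PV cKO). The replicate block called 2 (PV PTZ), 8 (SST PTZ), 2 (PV CFC) and 2 (SST CFC); replicate numbers did not pair libraries, with correlations of same-numbered libraries from -0.237 to 0.241. A sex term gave 0 (PV PTZ) and 10 (SST CFC), and leaving out PTZ libraries 1 and 2 gave 0 (PV PTZ). Leaving out home cage libraries 2 and 3 (SST CFC) left 1 home cage library, so that lost calls there say little. The vascular score gave 1 (SST CFC), and since it largely coincides with CFC, lost calls there say little too. Of 190 gene list tests 65 passed with camera, 5 with an estimated correlation and 21 with fry, which also called lists that camera did not. At an adjusted p under 0.1, overlaps held 1 gene (PV and SST CFC, higher), 11 (PV and SST cKO, higher) and 7 (lower). The cause was not tested for any of these changes.

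With 1 library left out, counts ran from 0 to 14 (PV PTZ), 13 to 17 (SST PTZ), 0 to 1481 (PV CFC), 1 to 37 (SST CFC), 7 to 1224 (PV cKO), 412 to 1292 (SST cKO), 5476 to 6982 (SST vs PV), 0 to 1 (PTZ, SST minus PV), 0 to 881 (CFC, SST minus PV), 0 to 9 (PV, CFC minus PTZ) and 0 to 59 (SST, CFC minus PTZ). A PV saline library left alone in batch 2, and the SST home cage library left alone, were assumed to vary like the other groups. Depth limits the PV saline libraries of batch 2 (6161764 and 4933110 counts) most.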

Other observations

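All tests in this part were chosen after the results were seen. Levels of Pvalb, the gene that drives Cre in the PV line, varied between batches in both cell types. In SST libraries it was at 7.85 ± 2.79 CPM (SD, n = 4) in saline of batch 2 and at 251 ± 202 CPM (n = 3) in the home cage of batch 4, where single libraries had 477, 189 and 87.7 CPM. In PV libraries it was at 20 ± 3.53 CPM (n = 3) in saline of batch 1, 302 ± 84.1 CPM (n = 2) in saline of batch 2 and 167 ± 18.2 CPM (n = 3) in the home cage of batch 3. Pvalb levels therefore do not separate the PV from the SST home cage libraries behind the CFC and cKO comparisons. Sst does, at 5750 ± 222 CPM (n = 3) in SST and 263 ± 167 CPM (n = 3) in PV home cage libraries. No explanation was tested for these levels.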
